A study of Mus musculus with 6 samples.

How the data were processed

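Microglia of mouse brain were profiled by nanopore cDNA sequencing in 6 libraries, 3 after sham surgery and 3 after tMCAO, each made from the pooled cells of 30 mice. The series description speaks of isolated microglia, while the extraction protocol speaks of tissue, and how cells were isolated is not given in the sources used here. Per that protocol, RNA was extracted with TRIzol and libraries were made with a PCR-based nanopore cDNA kit. The submitters' processing notes name minimap2, with no version. The genome build, the annotation, the counting rule and the use of strand are not given in the sources used here, so reads of overlapping or antisense genes could not be told apart and no coordinates are printed. Libraries are named by group and by the replicate number of the labels. The labels do not say which pools were prepared together, so p-values measure the spread between these pools.

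The deposited table holds raw read counts per gene and library, per the file headers, and beside them CPM columns, which the authors scaled by the total counts of each library. The deposited CPM differed from CPM computed here from counts and library totals by at most 4.87e-06. The table had 38219 lines, of which 12 held annotation text spilled from another line and no values, and were left out. The 38207 genes and loci were 22036 known genes with Ensembl mouse gene IDs, 15743 loci outside the annotation, 199 known long noncoding RNA genes and 229 such loci outside the annotation. No count in any library was recorded for 6471 of them, and 19 symbols stood on more than 1 line and were kept apart by ID. Of the Ensembl IDs, 22022 were in the GENCODE M21 table of gene names, and 99.9% of those had the same symbol there. No column was left without a sample.

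Genes were tested with edgeR 4.0.16 (R 4.3.3) on the deposited counts. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and robust dispersions and quasi-likelihood F tests (glmQLFit and glmQLFTest) were fitted with the group as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 13127 tested were called changed. The SE of a log2 fold change is its absolute value divided by the square root of the F statistic. The biological coefficient of variation was 22.6%. A fold against a group with no counts was bounded with 3 counts over the group. This applied to 3 changed genes.

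The 35 gene lists, the tests between the groups, the rule for named genes and 18 genes named in any case were chosen before the data were examined. Each list with at least 3 tested members was tested with camera (limma 3.58.1) against all other tested genes, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 30 lists tested. The calls with the preset correlation numbered 21, 13 higher and 8 lower, and 1 list was also called with a correlation estimated from its own members. With the estimate, camera also uses the few residual degrees of freedom of 6 libraries, which raises p whatever the correlation. The MHC list's estimate was -0.016, below the preset, yet its unadjusted camera p went from 1.24e-06 to 0.00621. Estimates were far above the preset for the cell cycle (0.63), mitochondrial genome (0.86) and erythroid lists (0.91), so their preset p-values are too small. Lists overlap: Apoe, for example, is in both the disease-associated microglia and the lipid list. Named genes are the 8 with the largest rise and the 8 with the largest fall, among called genes with an average log2 CPM of at least 4 and no overlap between the groups' libraries. Predicted models, genes without a symbol and immunoglobulin and T cell receptor segments were left out. This pool held 662 higher and 349 lower genes. To these were added up to 4 members of each list with the smallest p, and 18 microglial, inflammatory and cell-type genes fixed in advance. Igf1, Lyz2, Ly6c2 and the genes named with the libraries sham 1 and tMCAO 3 were chosen after their values were seen. The result of 1 gene that the rule names is not reported here.

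Differences between groups in library measures were tested with the two-sided exact permutation test of the difference of means over the 6 libraries. Its smallest p is 0.1. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.917 to 0.954 within groups and 0.849 to 0.882 between groups. A chi-square test of counts gave 4.64 to 9.02 per degree of freedom between replicates, so no pair lay within sampling noise of being 1 library deposited more than once.

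Depth ranged from 1855495 to 2614512 counts, at which 1 count is about 0.4 to 0.5 CPM. PCR reads carry no molecular identifiers, so counts are not independent molecules. The code was tested on counts simulated from the mean levels of the sham libraries and the totals of every library, with 11923 genes run and known folds. Of the changed genes, 23 of 93 (24.7%) were recovered at a fold of 2 and 79 of 88 (89.8%) at a fold of 4, with 4 false calls among 11742 unchanged genes. A simulated changed list was called, and 0 of 34 random lists were called by camera. Genes were simulated independently of each other, so this does not test false calls of lists with correlated members. Genes changed 2-fold or less can thus be missed at this depth and number of libraries. The share recovered does not carry over to these data, where 2380 of 13127 genes were called and far fewer were changed in the simulation. With fewer changed genes, the adjusted p sets a stricter threshold.

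The alternatives were DESeq2's size factors, upper-quartile scaling and library totals as scaling, no filter and a stricter filter (at least 10 counts in every library of a group), DESeq2 1.42.0, limma voom with quality weights, an absolute log2 fold change of at least 1, glmTreat against a fold of 1.5, the replicate number as a block, the 10 most abundant and the mitochondrial genes left out, each library left out in turn, and, for lists, an estimated correlation and at least 5 members. Chosen after seeing the data were known genes only, counts thinned to the smallest library, both sham 1 and tMCAO 3 left out, and a factor shared by those libraries. Ranges of adjusted p given for genes over the alternatives include glmTreat. It asks whether a change exceeds a fold of 1.5, so small changes have high values there. Transcript-level tests were planned in case the table held transcripts. Its lines are genes, so changed transcripts and transcript usage are not analysed here. Transcript sequences and pseudogenes of GENCODE M21 were used with minimap2 2.31-r1302 for checks of GC content, length and pseudogene copies. Values were handled with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1.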

Results

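cDNA of microglia isolated from mouse brain was sequenced on nanopores. Each of the 6 libraries pooled the cells of 30 wild-type mice, 3 pools after sham surgery and 3 after tMCAO (in its usual reading, transient middle cerebral artery occlusion, a model of ischemic stroke). Total counts were 2371235, 2522812 and 2614512 in sham libraries 1 to 3 and 2030550, 1855495 and 1877780 in tMCAO libraries 1 to 3. The time after surgery and the way the microglia were isolated are not given in the sources used here. Levels below are CPM (counts scaled by the library total), as mean ± SD of 3 libraries per group. Log2 fold changes compare tMCAO with sham and carry their standard error (SE), and adjusted p-values for genes come from edgeR's quasi-likelihood test.

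The 6 libraries separated by group. On the first principal component of log2 CPM, which held 54.1% of the variance, sham libraries lay between -49.6 and -43.0 and tMCAO libraries between 39.2 and 52.3. On the second (19.8%), tMCAO 3 stood apart at 50.6, against -31.4 and -24.3 for the other tMCAO libraries, and sham 1 was the sham library nearest to it at 18.0. Mitochondrial genes held 2.49 ± 0.793% of sham counts and 0.919 ± 0.106% of tMCAO counts. Genes of cytosolic ribosomal proteins held 14.4 ± 1.07% and 11.6 ± 0.351%. For both shares, for total counts and for the number of genes detected (28268 ± 301 and 26169 ± 630), the groups did not overlap. The two-sided exact permutation test gave p = 0.1 for each of these 4 measures (0.12 adjusted over 6 measures), which is the smallest value 3 libraries against 3 allow. The 10 most abundant genes held 17.8 ± 2.22% of sham counts and 15.4 ± 1.73% of tMCAO counts (exact permutation p = 0.2, 0.2 adjusted).

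**Figure D1:**
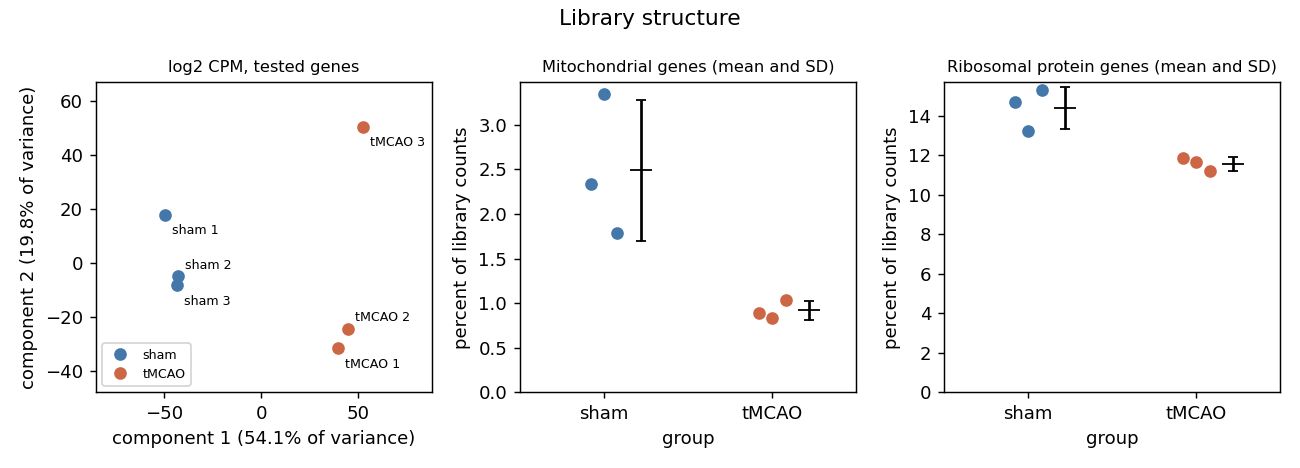
Left, the 6 libraries on the first 2 principal components of log2 CPM, with the percentage of variance on each axis. Middle and right, the share of each library's counts on mitochondrial genes and on cytosolic ribosomal protein genes, in percent (points, libraries; bars, mean and SD of 3). The 3 tMCAO libraries lie below all 3 sham libraries in both shares (means of 0.919% against 2.49% and 11.6% against 14.4%), and tMCAO 3 is apart on component 2.

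The comparison of tMCAO with sham addresses how gene expression in pools of brain microglia differs after ischemic stroke. In such bulk pools, a change within microglia cannot be told apart from a change in the cells pooled, such as other macrophages. Most tested interferon-stimulated, cell cycle and cytokine genes rose after tMCAO, as did part of the lipid-handling genes and of the genes of disease-associated microglia. As sets, these lists were called with a preset correlation between genes, and only the interferon list was also called with an estimated correlation. The estimate also leaves camera few degrees of freedom, so a lost call is not by itself a sign of correlated members. Part of the resting microglia genes, the genes of the mitochondrial genome and many ribosomal protein genes were lower. Markers of other cells moved too: the astrocyte, choroid plexus, erythroid and neutrophil lists were lower as sets, and the monocyte and border-associated macrophage lists higher, with the preset correlation. None of these lists of other cells was called with an estimated correlation. Spp1, which encodes the secreted matrix protein osteopontin (ENSMUSG00000029304), went from 11.5 ± 1.83 to 4892 ± 2277 CPM (log2 fold change 8.62 ± 0.62). Cst3, which encodes the protease inhibitor cystatin C (ENSMUSG00000027447), fell from 74994 ± 5271 to 30521 ± 3854 CPM (-1.42 ± 0.13).

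Of 13127 genes and loci tested, 2380 changed (18.1%), with 1204 higher and 1176 lower in tMCAO, so that 50.6% of the calls were higher. With library totals as the only scaling, 63.2% of the calls were higher, and the median log2 fold change of all genes shifted to 0.11. With upper-quartile scaling, 42.2% were higher (1043 higher, 1431 lower), and that median was -0.07. An absolute log2 fold change of at least 1 was reached by 1652 of the changed genes. The groups did not overlap for 4966 of the tested genes (37.8%), where chance gives 10%. Among annotated protein-coding and other known genes, 974 rose and 488 fell. Of the loci outside the annotation, 215 rose and 644 fell. The count of changed genes dropped to 1254 without sham 1 and to 1558 without sham 3, and was 1573 with both sham 1 and tMCAO 3 left out, a choice made after seeing the data.

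The largest rises among named genes were those of Gpnmb, Spp1, Cd5l, Saa3, Apoc2, Prc1, Ecm1 and Ch25h, with log2 fold changes from 9.27 down to 4.96. Gpnmb, a membrane glycoprotein of lipid-laden macrophages, had 0.797 ± 0.684 CPM in sham and 554 ± 523 in tMCAO (adjusted p = 0.0232), and its 3 tMCAO libraries held 129, 396 and 1139 CPM. Cd5l (8.35 ± 1.54, adjusted p = 0.0248), a macrophage-secreted apoptosis inhibitor, and Apoc2 (5.62 ± 1.03, adjusted p = 0.0244), the apolipoprotein that activates lipoprotein lipase, also rose. Their sham counts were 1, 0 and 0 for Cd5l and 12, 0 and 0 for Apoc2, so the size of both folds is uncertain, and with 1 library left out the log2 fold change of Cd5l ran from 7.41 to 10.12. Saa3, an acute-phase serum amyloid, rose from 0.532 ± 0.226 to 42.2 ± 14.4 CPM (6.04 ± 0.44). Ecm1, a secreted matrix protein, rose from 0.783 ± 0.793 to 36.8 ± 5.81 (5.31 ± 0.47), and Ch25h, the enzyme that makes 25-hydroxycholesterol, from 1.18 ± 0.993 to 42.0 ± 7.42 (4.96 ± 0.41). With edgeR's quasi-likelihood test, the call of Gpnmb was lost without sham 1, sham 2, sham 3 or tMCAO 2 (adjusted p from 0.0674 to 0.0975) and that of Cd5l without sham 1, sham 2, sham 3 or tMCAO 1 (0.0669 to 0.184). That of Apoc2 was lost without sham 2, sham 3, tMCAO 1 or tMCAO 2 (0.0522 to 0.0801), with a log2 fold change of up to 10.53. Over all alternatives, adjusted p ran from 1.91e-12 to 0.0975 for Gpnmb, from 2.78e-06 to 0.184 for Cd5l and from 0.000145 to 0.0801 for Apoc2.

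The largest falls were those of Slc1a2 (-4.25 ± 0.78), the glial glutamate transporter, Ccdc152 (-3.35 ± 0.58), Aldoc (-3.15 ± 0.58), the brain aldolase, Olfr839-ps1 (-2.96 ± 0.34), Mobp (-2.75 ± 0.57), a myelin protein, Olfr639 (-2.39 ± 0.31), Vmn2r114 (-2.30 ± 0.25) and Hspa1b (-2.18 ± 0.20), an inducible heat shock protein. Slc1a2, Aldoc and Mobp are markers of astrocytes or oligodendrocytes. Olfr839-ps1, Olfr639 and Vmn2r114 belong to the chemoreceptor families, and Hspa1b has a near-identical copy in Hspa1a, so counts assigned to each of these are uncertain. With edgeR's quasi-likelihood test, 4 of these calls were lost with a library left out. Slc1a2 lost it without sham 1, tMCAO 1, tMCAO 2 or tMCAO 3 (adjusted p from 0.0565 to 0.0965), Aldoc without any of the 3 tMCAO libraries in turn (0.0703 to 0.0959), Mobp without tMCAO 1 or tMCAO 3 (0.0562 to 0.0626) and Ccdc152 without tMCAO 3 (0.0746). With both sham 1 and tMCAO 3 left out, adjusted p was 0.191 for Slc1a2, 0.189 for Aldoc, 0.155 for Ccdc152 and 0.0679 for Mobp, the highest of all alternatives for each. The lowest were 3.75e-06, 4.05e-12, 2.38e-05 and 4.34e-12.

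**Figure D2:**
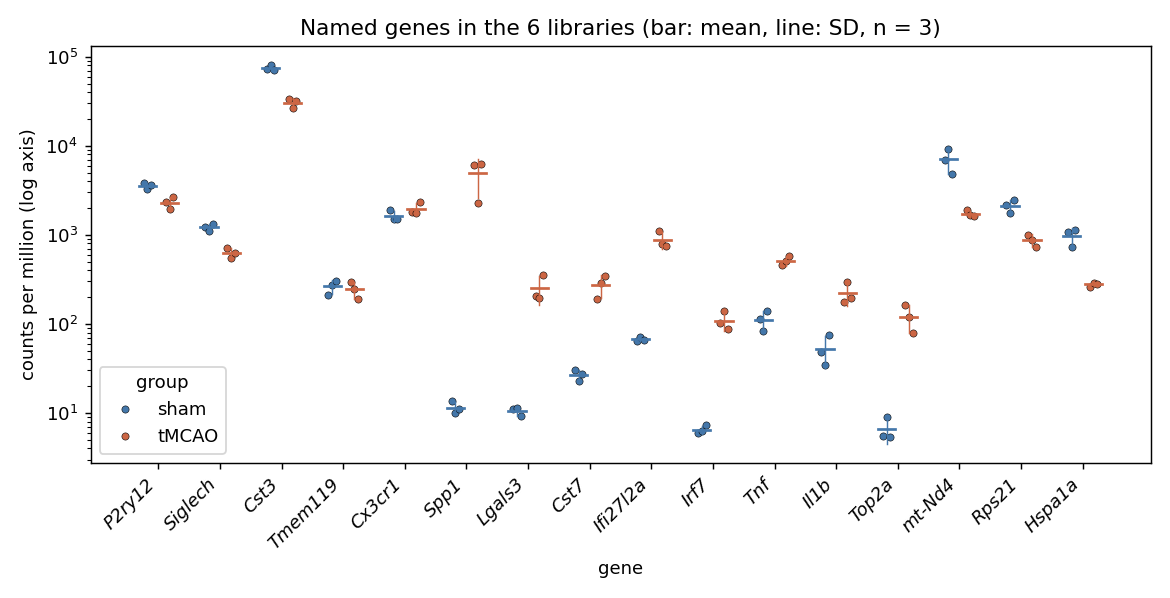
CPM of 16 named genes in each library (points), on a log axis, with the group mean (bar) and SD (line, n = 3). Spp1 had a mean of 11.5 CPM in sham and 4892 in tMCAO, while Tmem119 and Cx3cr1 overlapped between the groups.

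Among 28 genes of resting, homeostatic microglia, 11 fell, 0 rose and 17 did not pass the test. Adjusted over the list alone, 13 fell. Besides Cst3, the sialic acid receptor gene Siglech fell from 1217 ± 124 to 626 ± 78.6 CPM (-1.07 ± 0.14) and the purine receptor gene P2ry13 from 345 ± 49.3 to 178 ± 28.6 (-1.07 ± 0.18). P2ry12, the receptor by which resting microglia sense ADP, fell from 3562 ± 302 to 2300 ± 352 (-0.74 ± 0.15, adjusted p = 0.00482). Tmem119 (-0.24 ± 0.19), Cx3cr1 (0.16 ± 0.16), Sall1 (0.33 ± 0.18), Csf1r (0.35 ± 0.18) and Aif1 (-0.20 ± 0.16) did not pass the test. Without tMCAO 3, the value of Cx3cr1 was -0.01 and Csf1r passed edgeR's quasi-likelihood test at an adjusted p of 0.0424, as it did with no filter on low counts (0.0121, the lowest of its alternatives, which reached 1.00). As a set, the list was lower than other genes (median -0.32, camera adjusted p = 0.00162), with an adjusted p = 0.352 with an estimated correlation. The number of members that fell was 6 without sham 1 and 7 without tMCAO 2.

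Genes of disease-associated microglia, the state described in injury and neurodegeneration, rose in 15 of 30 measured members, and none fell. Adjusted over the list alone, 23 rose. Lgals3, which encodes galectin-3, rose from 10.5 ± 1.21 to 253 ± 89.9 CPM (4.48 ± 0.31), Cst7, an inhibitor of lysosomal proteases, from 26.8 ± 3.70 to 275 ± 79.3 (3.25 ± 0.25), and the phagocytic receptor kinase Axl from 4.39 ± 1.35 to 47.7 ± 21.7 (3.29 ± 0.36). Apoe, the main lipid carrier of the brain, had 1878 ± 1212 CPM in sham and 15036 ± 11499 in tMCAO, with 28314 in tMCAO 2, and did not pass edgeR's quasi-likelihood test (2.86 ± 0.96, adjusted p = 0.128). It passed with DESeq2 (0.00628) and with limma voom (0.00946), and its adjusted p reached 0.262 among the alternatives. Lpl, the lipoprotein lipase gene, had 134 and 156 CPM in tMCAO 1 and 2 and 598 in tMCAO 3, and did not pass (2.74 ± 0.78, adjusted p = 0.0846). It passed with DESeq2 (0.00331) and limma voom (0.0114), and without tMCAO 3 it passed edgeR's test (1.65, adjusted p = 7.70e-05, against 0.217 at most among the alternatives). Igf1 and Lyz2, picked after their values were seen, were likewise highest in tMCAO 3, at 337 and 6514 CPM against 117 and 2103 in tMCAO 2, and did not pass (adjusted p = 0.0587 and 0.0642 in edgeR's test). The list's median was 1.52, with a camera adjusted p of 2.26e-19 and an adjusted p = 0.0962 with an estimated correlation.

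Lipid uptake, storage and efflux genes rose in 11 of 21 members, with 17 adjusted over the list alone, and none fell. Of these 21, 8 are also in other lists, Apoe, Lpl and Ch25h among them. Plin2, the coat protein of lipid droplets, rose from 53.3 ± 11.4 to 585 ± 193 CPM (3.36 ± 0.28), the oxidized-lipoprotein receptor gene Olr1 from 2.53 ± 0.240 to 31.1 ± 12.2 (3.49 ± 0.39), and the scavenger receptor gene Msr1 from 4.26 ± 0.315 to 36.4 ± 12.1 (2.96 ± 0.30). Over the list, the median was 1.69, with a camera adjusted p of 1.52e-14 and an adjusted p = 0.0812 with an estimated correlation. Of 18 genes of cholesterol synthesis, 1 rose, and 1 did so adjusted over the list alone. That was Dhcr7 (1.57 ± 0.38, adjusted p = 0.0122 in edgeR's test), the last enzyme of the pathway, whose call was lost without sham 1 or sham 3 (0.0512 to 0.0544) and with 4 libraries (0.0821, the highest of alternatives that began at 0.000489). Fdps (-0.50 ± 0.26) did not pass. The cholesterol list did not pass (median 0.14, camera adjusted p = 0.528).

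Type I interferon response genes rose in 23 of 28 members, with 27 adjusted over the list alone, and none fell. Ifi27l2a rose from 67.2 ± 3.73 to 882 ± 196 CPM (3.59 ± 0.18), Irf7, the transcription factor that amplifies interferon production, from 6.50 ± 0.696 to 109 ± 26.6 (3.93 ± 0.24), and the RNA sensor gene Oas1a from 5.72 ± 0.887 to 64.7 ± 5.93 (3.37 ± 0.23). The list's median was 2.40 and its camera adjusted p was 1.42e-48. With an adjusted p = 0.0171 with an estimated correlation, this was the 1 list of 30 that passed both ways.

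Inflammatory cytokines and NF-kB targets rose in 20 of 26 members, with 23 adjusted over the list alone, and none fell. Tnf rose from 112 ± 27.4 to 514 ± 63.3 CPM (2.10 ± 0.19), Il1b from 52.4 ± 20.1 to 222 ± 62.1 (1.97 ± 0.27), the chemokine gene Cxcl2 from 38.7 ± 7.62 to 182 ± 48.8 (2.13 ± 0.23), and Tlr2, a receptor for bacterial lipoproteins, from 53.9 ± 3.98 to 219 ± 42.2 (1.90 ± 0.18). As a set, these genes had a median of 1.34, with a camera adjusted p of 5.13e-19 and an adjusted p = 0.0812 with an estimated correlation. The list of alternative activation and growth factors rose in the same libraries, in 10 of 16 members (12 adjusted over the list alone, none lower). Its examples were Csf1, a growth factor of microglia (2.16 ± 0.31), Osm, a cytokine of the interleukin-6 family (1.85 ± 0.26), and Cd36, a fatty acid and lipoprotein receptor (2.69 ± 0.45). That list's median was 1.26, with a camera adjusted p of 2.55e-08 and an adjusted p = 0.0812 with an estimated correlation. Without sham 1, 6 of its members rose.

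Antigen presentation genes (MHC class I and II) rose in 8 of 19 members, with 9 adjusted over the list alone, and none fell. Cd74, the invariant chain of class II, rose from 59.7 ± 11.2 to 230 ± 29.1 CPM (1.84 ± 0.19) and H2-Ab1, a class II chain, from 52.8 ± 12.95 to 197 ± 4.52 (1.79 ± 0.19). The class I genes H2-K1 (1.60 ± 0.21) and H2-Q7 (2.68 ± 0.41) also rose, but share sequence with other class I genes, so their counts are uncertain. The list's median was 0.57 (0.36 without sham 1), with a camera adjusted p of 3.09e-06 and an adjusted p = 0.0812 with an estimated correlation. Complement and phagocytic receptor genes rose in 12 of 24 members and fell in 0 (13 and 1 adjusted over the list alone). Complement factor B (Cfb) rose from 3.06 ± 0.789 to 67.6 ± 23.9 CPM (4.31 ± 0.32), C3, the central complement protein, from 2.82 ± 1.12 to 17.5 ± 0.631 (2.50 ± 0.37), and Itgb2, the beta chain of complement receptor 3, from 108 ± 14.2 to 255 ± 15.5 (1.13 ± 0.16). That list's median was 0.54, with a camera adjusted p of 6.26e-08 and an adjusted p = 0.0812 with an estimated correlation.

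Cell cycle genes rose in 28 of 30 members, with 29 adjusted over the list alone, and none fell. Top2a, which untangles replicated DNA, rose from 6.65 ± 2.14 to 121 ± 41.8 CPM (4.04 ± 0.30), Birc5, an inhibitor of apoptosis in dividing cells, from 1.73 ± 0.229 to 33.0 ± 11.2 (4.08 ± 0.36), and Nusap1, a spindle protein, from 1.87 ± 0.304 to 33.2 ± 8.79 (3.99 ± 0.34). Prc1, which bundles the microtubules of the dividing spindle, rose from 0.941 ± 0.281 to 51.6 ± 18.5 (5.59 ± 0.39). Over the list, the median was 3.70, also with the 1 member that had no sham count at its bound. Its camera adjusted p was 1.24e-45, with an adjusted p = 0.0812 with an estimated correlation.

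**Figure D3:**
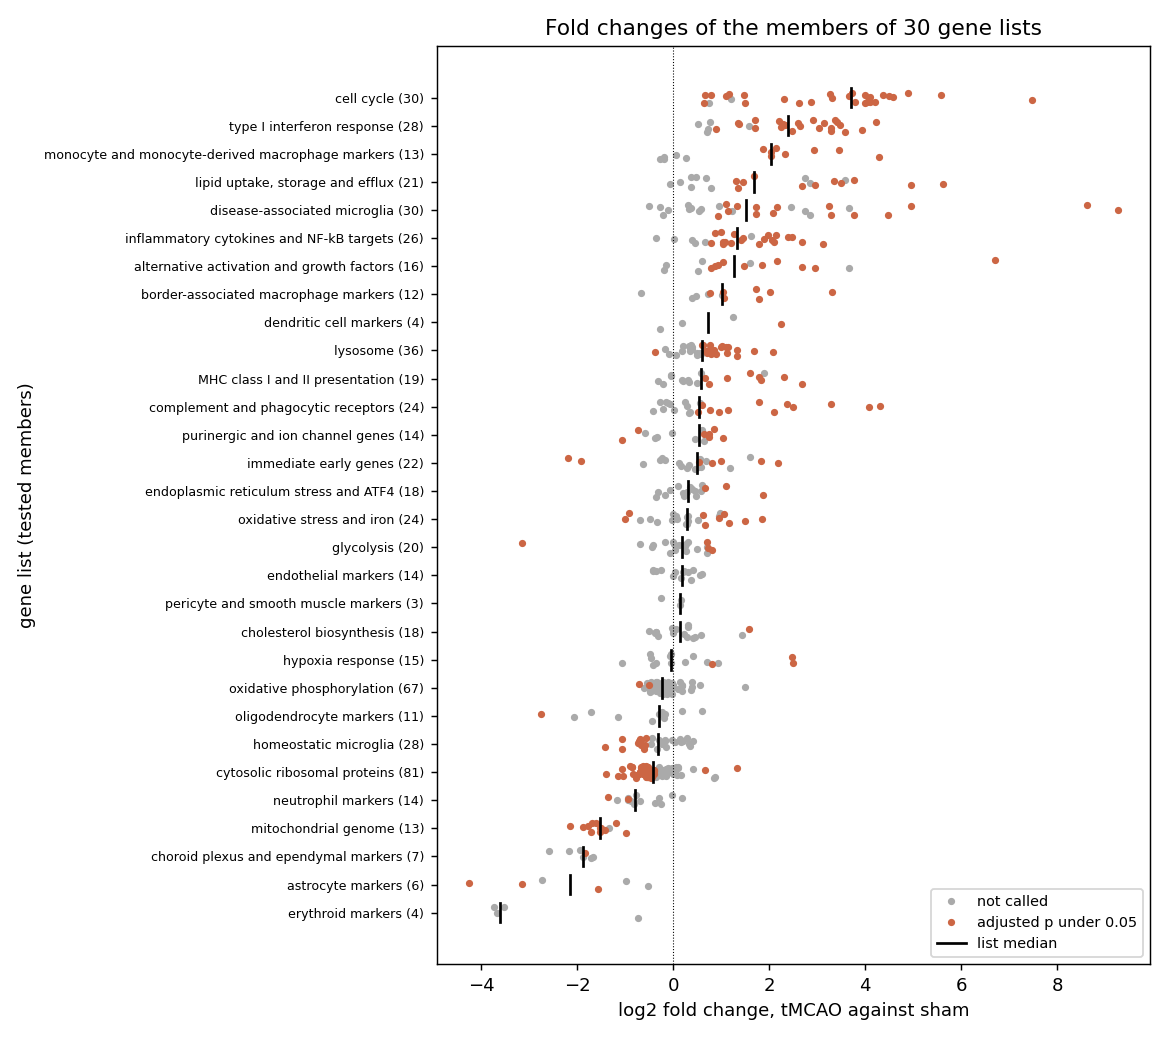
Log2 fold change, tMCAO against sham, of each tested member of the 30 gene lists with at least 3 tested members (points; orange, adjusted p under 0.05 in edgeR's test; grey, not called), with each list's median (bar). Medians ran from 3.70 for the cell cycle to -3.60 for erythroid markers.

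The 13 protein genes of the mitochondrial genome fell in 12 members, and 13 adjusted over the list alone. mt-Nd4, a subunit of respiratory complex I, fell from 7033 ± 2217 to 1729 ± 145 CPM (-2.15 ± 0.24), mt-Nd2 from 1351 ± 374 to 453 ± 39.3 (-1.70 ± 0.21) and mt-Nd3 from 134 ± 42.0 to 39.5 ± 5.96 (-1.89 ± 0.24). Their summed levels in sham 1 to 3 (23311, 33504 and 17887 CPM) followed the same order as those of the astrocyte (408, 666 and 187), choroid plexus (13941, 44575 and 8611) and erythroid markers (2888, 6076 and 972), and all 4 sums were lower on average in tMCAO. In tMCAO 1 to 3, the mitochondrial sums (8900, 8299 and 10361) followed the order of the erythroid sums (311, 233 and 394). They did not follow the astrocyte (86.7, 126 and 96.4) or choroid plexus sums (2271, 4042 and 9938). This comparison of orders was not planned, and orders of so few libraries can agree by chance. Without sham 2, the median of the mitochondrial list was -1.24. As reported, it was -1.53, with a camera adjusted p of 2.60e-14 and an adjusted p = 0.19 with an estimated correlation. Of 67 nuclear genes of oxidative phosphorylation, 2 fell and 0 rose, and 0 did adjusted over the list alone in edgeR's test, where 15 were lower and 2 higher at an unadjusted p under 0.05. DESeq2 called 1 lower and limma voom 5. The 2 that fell were Ndufa8 (-0.71 ± 0.16, adjusted p = 0.00964) and Uqcrh (-0.50 ± 0.16, adjusted p = 0.0409). The call of Ndufa8 was lost without sham 1 (0.0536) and that of Uqcrh without any library but tMCAO 3 (0.0712 to 0.145). Their alternatives, among them glmTreat's test for a fold above 1.5, ran from 0.00402 to 0.392 and from 0.0183 to 0.913. The oxidative phosphorylation list's median was -0.23, with a camera adjusted p of 0.0187 and an adjusted p = 0.742 with an estimated correlation. Its call was also lost without sham 2 (median -0.10, 0.483), tMCAO 1 (-0.24, 0.0737) or tMCAO 2 (-0.12, 0.351) and with no filter (0.137). Without tMCAO 3 its median was -0.36, and 10 of its members fell.

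Glycolysis genes did not move as a set (median 0.19, camera adjusted p = 0.414): of 20, 3 rose and 1 fell, and the same numbers did adjusted over the list alone. Ldha, which converts pyruvate to lactate, rose from 216 ± 8.68 to 408 ± 65.0 CPM (0.81 ± 0.17, adjusted p = 0.00656), while Aldoc, also an astrocyte marker, fell. Pgam1 (0.73 ± 0.23, adjusted p = 0.0405) lost its call in edgeR's test without any library but sham 2 (0.0544 to 0.156), and Pfkfb3 (0.70 ± 0.23, adjusted p = 0.047) without each of the 6 in turn (0.0513 to 0.130). Their alternatives ran from 0.0114 to 0.445 and from 0.0277 to 0.494. Of 15 targets of hypoxia-inducible factors, 3 rose and 0 fell (3 and 2 adjusted over the list alone), and the list did not pass, with a median of -0.05, a mean of 0.34 and a camera adjusted p of 0.414 in the higher direction. Besides Ldha, these were the lipid droplet gene Hilpda (2.47 ± 0.49, adjusted p = 0.0144) and the transcription factor gene Bhlhe40 (2.51 ± 0.58, adjusted p = 0.0147). The call of Hilpda was lost without sham 1, sham 2, sham 3 or tMCAO 2 (0.0515 to 0.0653) and that of Bhlhe40 without sham 2 or sham 3 (0.0555 to 0.0616). Those were the highest of alternatives that began at 8.89e-21 and 7.35e-08.

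Lysosome genes rose in 18 of 36 members and fell in 1 (24 and 1 adjusted over the list alone). Grn, which encodes progranulin, rose from 721 ± 119 to 1966 ± 112 CPM (1.34 ± 0.15), the protease gene Ctsz from 1006 ± 89.8 to 2383 ± 289 (1.14 ± 0.15), and Atp6v0c, a proton pump subunit, from 646 ± 68.9 to 1410 ± 110 (1.01 ± 0.14). As a set, these genes had a median of 0.60, with a camera adjusted p of 1.30e-08 and an adjusted p = 0.312 with an estimated correlation. Without sham 3, 10 members rose. Oxidative stress and iron genes rose in 7 of 24 members and fell in 2 (8 and 2 adjusted over the list alone). Ftl1, the ferritin light chain, rose from 4007 ± 585 to 8993 ± 1111 CPM (1.06 ± 0.15), Cybb, the catalytic subunit of the phagocyte oxidase, from 19.8 ± 1.54 to 77.3 ± 12.9 (1.86 ± 0.21), and the metallothionein gene Mt2 from 24.8 ± 8.13 to 75.4 ± 19.5 (1.49 ± 0.29). The camera adjusted p of the oxidative stress and iron list was 0.0187 (median 0.29), with an adjusted p = 0.352 with an estimated correlation. It was 0.0586 without sham 1, 0.0792 without sham 3 and 0.0942 with known genes alone, and 4 members rose without sham 1 or without sham 3.

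Endoplasmic reticulum stress and ATF4 genes rose in 3 of 18 members, and in 3 adjusted over the list alone. Psat1, an enzyme of serine synthesis, rose from 26.1 ± 3.83 to 103 ± 24.7 CPM (1.87 ± 0.23), Ppp1r15a, which ends the stress-induced block of translation, from 291 ± 46.5 to 669 ± 123 (1.09 ± 0.18), and Ddit3, the stress transcription factor CHOP, from 111 ± 12.6 to 191 ± 16.4 (0.67 ± 0.16, adjusted p = 0.011 in edgeR's test). The call of Ddit3 was lost without sham 1 or sham 2 (0.0504 to 0.0633), in a range of alternatives from 0.000661 to 0.492. The list's median was 0.32, with a camera adjusted p of 0.0438 and an adjusted p = 0.338 with an estimated correlation. The call of the endoplasmic reticulum stress and ATF4 list was also lost without sham 1 (median 0.18, 0.178), without tMCAO 1 (0.18, 0.0713), with known genes alone (0.177) and with counts thinned to the smallest library (0.055). It was lost with the replicate number as a block too.

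Immediate early genes, which dissociation of tissue can also induce, rose in 5 of 22 members and fell in 2 (8 and 3 adjusted over the list alone), and the list did not pass (median 0.50, camera adjusted p = 0.158). Nr4a1 rose from 53.3 ± 10.4 to 206 ± 22.9 CPM (1.83 ± 0.19) and Nfkbid, a nuclear regulator of NF-kB, from 9.36 ± 2.96 to 47.1 ± 17.7 (2.19 ± 0.31). The heat shock genes Hspa1a (982 ± 216 to 278 ± 14.01 CPM, -1.93 ± 0.17) and Hspa1b fell, and the division of their counts is uncertain. The immediate early genes passed as a set without tMCAO 3 (0.00243), where 11 members rose, without sham 3 (0.0367), with no filter (0.00606) and with both sham 1 and tMCAO 3 left out (0.00475). Without sham 1 or sham 2, 3 members rose. The members Junb (63.9 CPM in tMCAO 3 against 622 and 726) and Ier2 (25.0 against 261 and 250), picked after their values were seen, belong to the genes low in both sham 1 and tMCAO 3. Purinergic and ion channel genes went both ways, with 5 of 14 higher and 2 lower (7 and 3 adjusted over the list alone), and did not pass as a set (median 0.53, camera adjusted p = 0.391). Against the falls of P2ry12 and P2ry13, the uridine diphosphate receptor gene P2ry6 rose from 116 ± 14.7 to 211 ± 10.7 CPM (0.75 ± 0.16) and the calcium channel gene Trpm2 from 18.8 ± 5.33 to 41.7 ± 6.25 (1.04 ± 0.25). Trpm2 had an adjusted p of 0.0527 in edgeR's test with both sham 1 and tMCAO 3 left out. Its alternatives, glmTreat among them, ran from 0.000199 to 0.120. Of the purinergic and ion channel genes, 2 rose without sham 2 and 3 without sham 3.

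Cytosolic ribosomal protein genes fell in 45 of 81 members and rose in 2 (52 and 2 adjusted over the list alone). Rps21 fell from 2132 ± 345 to 872 ± 138 CPM (-1.41 ± 0.15), Rplp1 from 6006 ± 732 to 2948 ± 425 (-1.15 ± 0.13) and Rps15 from 2141 ± 181 to 1248 ± 66.6 (-0.90 ± 0.12). Ribosomal protein genes have many processed pseudogenes, so the counts of single members are uncertain. Over the list, the median was -0.42 (-0.31 with library totals as the only scaling), with a camera adjusted p of 1.14e-07 and an adjusted p = 0.335 with an estimated correlation. The members that fell numbered 25 without sham 1, 27 without sham 3 and 29 without tMCAO 2.

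Markers of other cells moved in different directions. Of 13 tested monocyte and monocyte-derived macrophage markers, 8 rose and 0 fell, also adjusted over the list alone (median 2.04, camera adjusted p = 2.01e-07, adjusted p = 0.183 with an estimated correlation). Vim, an intermediate filament gene, rose from 9.43 ± 2.51 to 51.8 ± 8.26 CPM (2.32 ± 0.26), Thbs1 from 2.79 ± 0.265 to 33.8 ± 17.3 (3.45 ± 0.39), Plac8 from 4.65 ± 0.471 to 22.6 ± 8.62 (2.15 ± 0.34), and Ccr2, the chemokine receptor of inflammatory monocytes, from 2.55 ± 0.730 to 10.3 ± 1.43 (1.88 ± 0.39, adjusted p = 0.0056). Ly6c2, the classical surface marker of those monocytes, picked after its values were seen, was at 12.3 ± 1.26 and 14.01 ± 6.65 CPM (0.06 ± 0.33) and did not pass. Border-associated macrophage markers rose in 7 of 12 members (8 higher and 1 lower adjusted over the list alone), with a median of 1.02, a camera adjusted p of 9.29e-06 and an adjusted p = 0.0812 with an estimated correlation. Among them, the coagulation factor gene F13a1 rose from 19.4 ± 6.28 to 69.0 ± 5.76 CPM (1.72 ± 0.23), the folate receptor gene Folr2 from 3.48 ± 1.65 to 37.2 ± 16.7 (3.31 ± 0.44), and the mannose receptor gene Mrc1 from 33.0 ± 4.99 to 73.9 ± 21.6 (1.04 ± 0.22).

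Neutrophil markers fell in 2 of 14 members, and in the same number adjusted over the list alone, Retnlg (70.3 ± 7.50 to 39.5 ± 12.97 CPM, -0.95 ± 0.22) and Lcn2 (-1.35 ± 0.34, adjusted p = 0.028). S100a8, the most abundant at 1040 ± 160 and 505 ± 347 CPM, did not pass edgeR's test (-1.16 ± 0.57, adjusted p = 0.24) unless tMCAO 1 was left out (0.0306, against 0.536 at most), but passed with limma voom (0.0475). The call of Lcn2 was lost without sham 2, sham 3 or tMCAO 3 (0.0749 to 0.110), and that of Retnlg with both sham 1 and tMCAO 3 left out (0.0533). Their alternatives, glmTreat among them, ran from 3.30e-08 to 0.114 and from 0.000737 to 0.148. The neutrophil markers had a median of -0.80 (-0.43 without tMCAO 2), with a camera adjusted p of 0.0156, 0.0775 without tMCAO 2, and an adjusted p = 0.526 with an estimated correlation.

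Astrocyte markers fell in 3 of 6 tested members, Slc1a2, Aldoc and S100b (-1.57 ± 0.47, adjusted p = 0.0353), and in 5 adjusted over the list alone. The number that fell was 6 of 7 without sham 3, 1 without sham 1 or tMCAO 1, 2 without sham 2, and 0 without tMCAO 2, without tMCAO 3 or with both sham 1 and tMCAO 3 left out. The S100b call was lost in edgeR's test without sham 1, sham 2, tMCAO 2 or tMCAO 3 (0.0933 to 0.130) and with library totals alone (0.0562), in a range from 0.00604 to 0.161. The astrocyte list had a median of -2.16, a camera adjusted p of 0.000588 and an adjusted p = 0.352 with an estimated correlation. Choroid plexus and ependymal markers fell in 1 of 7 members, Clic6 (-1.84 ± 0.53, adjusted p = 0.0288), which lost its call without sham 2, sham 3, tMCAO 1 or tMCAO 2 (0.0562 to 0.123, in a range from 0.00358). Ttr, the transport protein transthyretin, had 21250 ± 18356 and 5101 ± 3800 CPM and did not pass (-2.17 ± 1.01). The choroid plexus and ependymal markers had a median of -1.88, a camera adjusted p of 0.0233 and an adjusted p = 0.527 with an estimated correlation, and were not called without sham 2 (median -0.77, 0.0921). Adjusted over the list alone, 1 of them fell too, and over all genes 4 of 9 fell without sham 3 and 0 without sham 2, tMCAO 1 or tMCAO 2. Of 4 erythroid markers, 0 passed edgeR's test over all genes and 4 fell adjusted over the list alone, as 4 did at an unadjusted p under 0.05. DESeq2, which tested more of the list, called 5 lower and limma voom 3. In edgeR's test over all genes, 4 of 5 fell without sham 3, 3 of 4 with known genes alone, and 1 with library totals alone or without sham 2, tMCAO 1 or tMCAO 3. The list's median was -3.60 and its camera adjusted p was 0.00483 (adjusted p = 0.352 with an estimated correlation). The globin gene Hba-a2, whose copies are near-identical, had 1829 ± 1418 and 174 ± 47.9 CPM and did not pass edgeR's test (-3.53 ± 0.85, adjusted p = 0.059) unless sham 3 was left out (0.00803) or known genes alone were used (0.0479). It passed with DESeq2 and limma voom (in a range from 0.000131 to 0.254). Sham 2 was the highest library for Ttr (42248 CPM), Hba-a2 (3349), Slc1a2 (129) and Mbp (234).

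Oligodendrocyte markers fell in 1 of 11 members, Mobp, as did 1 adjusted over the list alone. They did not pass as a set (median -0.29, camera adjusted p = 0.212), although they did without sham 3 (median -0.84, 0.00733) and with the replicate number as a block. Mbp, a major myelin protein, was at 125 ± 96.0 and 32.9 ± 12.6 CPM (-2.08 ± 0.71, adjusted p = 0.122 in edgeR's test). It passed without sham 2 or sham 3 (0.0210 to 0.0467), with DESeq2 (0.0435) and with limma voom (0.0456, in a range from 0.00167 to 0.351). Endothelial markers changed in 0 of 14 members in edgeR's test, also adjusted over the list alone, in 0 with DESeq2 and limma voom, and in 1 at an unadjusted p under 0.05 (median 0.18, camera adjusted p = 0.901). Cldn5, a tight junction protein of brain vessels, was at 23.7 ± 18.9 and 26.4 ± 22.6 CPM (-0.01 ± 1.06), and was lowest in sham 1 (4.22 CPM) and tMCAO 3 (5.86 CPM), which share a set of low genes. The endothelial markers passed without tMCAO 1 (median 0.59, 0.0408), where 2 members rose. Of 3 pericyte and smooth muscle markers, 0 passed with edgeR, DESeq2, limma voom or at an unadjusted p under 0.05 (median 0.15, mean 0.02, camera adjusted p = 0.949 in the lower direction). Dendritic cell markers rose in 1 of 4 members and in 2 adjusted over the list alone, with Cd209a at 1.75 ± 0.697 and 9.17 ± 1.41 CPM (2.25 ± 0.43). The dendritic cell markers did not pass as a set (median 0.71, camera adjusted p = 0.128), nor in 10 of 15 alternatives. Those in which they passed included leaving out sham 1 (1.29, 0.0416), sham 2 (1.58, 0.0277) or tMCAO 3 (1.23, 0.0291) and no filter (0.00756). Fewer than 3 members were tested, so that no set test was made, for fibroblast markers (Igfbp2 at -2.40 ± 1.03 and Dcn at -0.02 ± 0.52, 0 of 2 called by edgeR, 0 at an unadjusted p under 0.05 and 1 lower with DESeq2), T and NK cell markers and B cell markers (Cd79b at -0.20 ± 0.26, not called). The 1 tested T and NK cell marker was the chemokine gene Ccl5, which is also in the cytokine list and rose from 18.9 ± 6.20 to 115 ± 27.1 CPM (2.48 ± 0.24). No neuron or oligodendrocyte precursor marker had enough counts to be tested, and together the neuron markers summed to 28.2 CPM in sham and 13.5 in tMCAO. Snap25, of synaptic vesicle fusion, was at 2.17 ± 1.12 and 1.04 ± 0.545 CPM, and the astrocyte filament gene Gfap at 3.33 ± 2.63 and 1.40 ± 0.654.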

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

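The alternatives of known genes only, thinned counts, both sham 1 and tMCAO 3 left out, and a factor shared by those libraries were chosen after seeing the data, and the others were planned. Of the 95 named genes called, 68 kept direction and call under every alternative, 27 lost the call under at least 1 and 0 reversed. Leaving out libraries one at a time ended the call of 18 of them. Of the 21 lists called, 1 (type I interferon response) kept its call everywhere and 0 reversed.

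The count of changed genes (2380, 1204 higher and 1176 lower) rose with no filter to 4039, 2053 and 1986, where more genes are tested, and was 874, 487 and 387 with glmTreat, whose null hypothesis is wider. DESeq2 called 1658 genes, 693 of them lower. Known genes only gave 1493 changed and 622 lower, with fewer genes tested and the scaling set on known genes alone. In the fit of all genes, 488 known genes were lower. The median log2 fold change of known genes was 0.0939 there and 0.0388 with known genes only. With both sham 1 and tMCAO 3 left out, 1573 changed and 652 were lower, with fewer samples. Leaving out each library in turn gave 1254 to 2590 changed, 700 to 1423 higher, 554 to 1167 lower and 19 to 23 lists called. The estimated correlation, which also lowers camera's degrees of freedom, called 1 list, against 21. Of the reported calls, 2063 kept their direction and call with library totals only and 1503 with DESeq2.

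Directions reversed in these results, of which edgeR or camera called 0 as reported, and the cause was not tested. The hypoxia list's median (-0.05) was 0.0712 with library totals only, 0.23 with no filter, where it was called (0.0363), and 0.0546 with the shared factor. Leaving out libraries in turn gave -0.0950 to 0.245, above 0 without sham 2, tMCAO 1 or tMCAO 2. Leaving out libraries, the cholesterol list's median ran from -0.0289 (without sham 3) to 0.254, the oligodendrocyte list's from -0.837 to 0.157 (above 0 without sham 2) and the endothelial list's from -0.321 (below 0 without tMCAO 2) to 0.586. That of the pericyte list ran from -0.469 to 0.541, and was below 0 without sham 1 (-0.00231) or tMCAO 2. Cx3cr1 ran from -0.00765 (without tMCAO 3) to 0.273. Cldn5 (-0.01) was 0.14 with library totals only, 0.0541 with no filter, 0.0202 with the stricter filter, 0.0122 with DESeq2, 0.674 with limma voom, 0.0298 with the shared factor and between -0.847 and 0.726 with 1 library left out, and is among the 35 genes low in both sham 1 and tMCAO 3.

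The replicate numbers did not pair the libraries: the deviations of same-numbered libraries from their group means correlated at -0.21, 0.02 and -0.17, and 0 of 6 libraries were closest to their own number. With the replicate number as a block, 1662 genes were called, 834 higher and 828 lower, of which 1618 were among the reported calls in the same direction. With the block, 21 lists were called, with the endoplasmic reticulum stress and ATF4 list no longer called (0.0665 against 0.0438) and the oligodendrocyte list called (0.0279 against 0.212), the hypoxia list's median was 0.0390 and the log2 fold change of Cldn5 was 0.0451. The alternative of the most abundant transcript and all transcript-level tests were not run, since the table holds genes. At this depth changes of 2-fold or less can be missed. In the simulation 23 of 93 2-fold changes were recovered, but far fewer genes were changed there than were called in these data. Genes that did not reach about 10 counts in at least 3 libraries were not tested. A gene with few counts in 1 group could thus be tested through the other, as Cd5l was (sham counts 1, 0 and 0).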

Other observations

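The tests of technical explanations in this part were chosen after the patterns were seen, except the count of other splits of the libraries.

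Long noncoding RNA genes and loci outside the annotation leaned lower in tMCAO. Of 113 known long noncoding RNA genes tested, 7 rose and 14 fell, and of 145 such loci outside the annotation, 8 rose and 30 fell. All loci outside the annotation together held 15.04, 11.87 and 15.09% of the counts of sham 1 to 3 and 11.86, 13.36 and 11.09% of those of tMCAO 1 to 3 (exact permutation p = 0.2).

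Odorant, vomeronasal and other chemoreceptor genes fell together with loci outside the annotation. Of 42 chemoreceptor genes tested, 34 fell and 0 rose with edgeR (median log2 fold change -1.82), with a sum of 2039 ± 527 CPM in sham and 729 ± 121 in tMCAO (SD, n = 3, exact permutation p = 0.1, the smallest possible). In the fit of all genes, 75.0% of the changed loci outside the annotation were lower, against 33.4% of changed known genes. The share for known genes depends on the fit: with known genes only, 871 rose and 622 fell. The greater depth of the sham libraries is excluded as the whole cause, since 74.6% of the 696 such loci that changed after thinning to equal totals were lower. A background equal for every chemoreceptor gene is excluded as the whole cause too. Of chemoreceptor counts, 58.2% lay in the 10 most abundant genes (an even spread gives 0.635%). A background that differs between genes was not tested. Of the tested chemoreceptor genes, 69.0% lay within 2 SE of their median. By a cutoff set after the pattern was seen, this argues against a single factor acting alike on all their counts as the whole cause. A factor acting on part of each gene's counts would also spread the fold changes, so the test cannot exclude it. An uneven background, reads from neighbouring or overlapping transcripts assigned to these genes, and a response of the cells to ischemia may explain the pattern, and none of them was tested.

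Markers of monocytes and of border-associated macrophages rose in tMCAO, in 8 of 13 and 7 of 12 tested members. A lower share of microglia in the tMCAO pools, with the other cells in unchanged proportions, would raise the markers of every other cell type alike. The mean change in log2(CPM + 1) was -0.615 ± 0.290 for all 67 tested markers of other cell types. For the 25 of these lists it was 1.33 ± 0.133, a difference of -1.94 ± 0.332 (SE over libraries). With 1 library left out, the difference ran from -2.13 to -1.69. These values argue against that case as the whole cause. They cannot decide on a microglial share lowered by added macrophages, which would raise these lists alone. Entry of Ly6c2-positive monocytes predicts a rise of Ly6c2 with Ccr2 and Plac8, but Ly6c2 had a log2 fold change of 0.0638 ± 0.328, more than 2 SE below the rise of at least 1 looked for, and is left open because its sham level (12.3 CPM, against 2.55 for Ccr2) can hide a small share of such cells. Of the 13 tested monocyte markers, 13 had counts in every sham library and 1 is in another list, and of the 12 border-associated macrophage markers, 12 and 2. Matured macrophages from blood and a change in the microglia themselves may both raise these genes, and both stay open, as how the cells were isolated is not given in the sources used here.

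Sham 1 and tMCAO 3, from different groups, shared a set of low genes. Of 5207 known genes with a mean of at least 15 CPM, 35 were in both libraries more than 4-fold below the mean log2(CPM + 1) of the other 2 libraries of the group, among them Cldn5, Tpt1 (328 CPM in sham 1 against 4559 and 4399, and 217 in tMCAO 3 against 2396 and 2074), Itm2b, Pdia3, Clta and Rps2, where 0.905 are expected if independent and the other 8 pairs reached 1 at most. Processed pseudogenes are excluded as the whole cause, since 11.4% of the 35 have a copy against 6.38% of other genes (Fisher's exact p = 0.281), and so is a shortfall of long transcripts, since their median transcript length was 1809 bases against 3136.5. The first 300 bases of their transcripts had a median GC content of 67.7% against 59.0% (permutation p = 1e-05, the smallest the permutations can give), so poorer recovery of GC-rich 5' ends in these libraries is a candidate explanation. No biological explanation was tested, since the libraries are from different groups. By edgeR, 0 of the 35 were called between the groups, but their selection for gaps within both groups widens their spread, so a call was unlikely. By the same criterion, tMCAO 3 had 124 low genes, against 5 and 3 in tMCAO 1 and 2. Sham 1 had 38, against 0 and 6 in sham 2 and 3.

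Among the 10 splits of the 6 libraries into 3 and 3, the real 1 gave 2380 changed genes and the highest of the others 0 with edgeR (592 at an unadjusted p under 0.05, and 23 with DESeq2). With 10 splits, a share under 0.05 cannot be reached. Every other split also mixes sham and tMCAO libraries on both sides, so the group difference widens the spread there and few calls were likely. The counts of the other splits therefore do not show how many calls arise without a group difference.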
